A study of Mus musculus with 9 samples.

How the data were processed

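Poly(A) RNA from 9 mouse livers was sequenced with a stranded protocol, 3 mice in each of 3 labelled groups, after 16 weeks of a high-fat diet. Per the labels and the submitters' processing notes, read quality was checked with FastQC, reads were aligned to mm10 with HISAT2 2.1.0, and differential expression was run with DESeq2; those differential results were not used here. Per the file headers, the deposited table holds raw counts per gene and library from featureCounts 1.6.2 with the reverse-strand setting (2), and a Length column with each gene's length in bases, a unit of other kind that was not used for scaling. The table has 23337 genes named by symbol, and every column of values was matched to a sample. Depth ran from 18683660 to 30509242 assigned reads per library, and TMM factors from 0.883 to 1.10. No batch, date or cage is given by the labels. Pearson r of log2 CPM between replicates was 0.984 to 0.991 in WT, 0.949 to 0.974 in dHep and 0.974 to 0.989 in KO, across genes, which are not independent replicates.

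Genes were kept by filterByExpr of edgeR (minimum count 10, minimum total 15), which left 13141. All 9 libraries entered 1 quasi-likelihood fit of edgeR 4.0.16 (R 4.3.3) on raw counts with TMM factors and a mean per group. The 3 contrasts were dHep minus WT, KO minus WT and KO minus dHep; a p was adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values are reads of a gene scaled to a library of 1e+06 reads, with TMM-scaled library sizes. Ranks of 3 against 3 cannot reach a two-sided exact permutation p under 0.1, so the tests rest on the spread shared across genes. The test was tried on simulated data with the study's own means and dispersions: edgeR found 60%, 57% and 61% of genes changed 2-fold and 81%, 90% and 85% of those changed 4-fold in the 3 comparisons, with 9, 4 and 10 false calls.

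Before the data were examined, 35 gene lists with 903 symbols were fixed from textbook knowledge; 868 symbols were in the table and 717 different genes were tested. The list of mitochondrially encoded mRNAs had 0 members in the table, which left 34. Each list was compared with all other genes by camera of limma 3.58.1 with a preset correlation of 0.01 between genes, and again with an estimated correlation; a camera p was adjusted over the lists of a comparison by the Benjamini-Hochberg method. A count described as adjusted over the list alone uses p values adjusted among the members of that list. For a group with no read, the fold is a lower bound against a floor of 3 reads over the group; for 1 to 3 reads a ratio with its 95% counting interval is given. Floors and intervals cover counting error only. Reads carry no molecular identifiers.

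The named genes were set before the data were examined: 10 readouts, of which 8 are reported here (F2rl1, Hnf4a, Alb, Cyp7a1, Apob, Fasn, Cd36 and Col1a1), the 6 largest rises and 6 largest falls among called genes with a mean of at least 1 CPM and no overlap of the 2 groups, and up to 2 called genes per direction of each list. Of the genes from the lists, a subset is printed, set after the data and the results of the alternatives had been seen: called genes with the smallest p in the direction of the list test, 2 for the 6 lists with the lowest list p and 1 for the other lists past the threshold. Apoa4, Egr1 and the sex-linked genes are named besides, as are some called genes that moved against the direction of their list. Of 113 called named genes in dHep against WT, 79 passed under every alternative that gave a value, of 114 in KO against WT 102, and of 77 in KO against dHep 32. The correlation and covariance of changes against WT, in dHep and in the libraries labelled KO, were compared with 20 simulated data sets. These had no group effects and shared the WT libraries.

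The alternatives fixed beforehand were median-of-ratios size factors in edgeR, the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, no low-count filter, a stricter filter (1 CPM in at least 3 libraries), only the 2 compared groups in the fit, the replicate number as a block, and leaving out each library in turn. Leaving out WT replicate 1 and dHep replicate 2 together was added after the data were seen. Genes removed by a filter, or given no adjusted p by DESeq2, have no value under that alternative, and list tests were not run with DESeq2 or limma voom. Positions come from an mm10 annotation; F2rl1 was counted as a whole gene, since the table gives no counts per exon.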

Results

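Messenger RNA was measured by stranded poly(A) sequencing in the livers of 9 C57BL/6 mice that had received a high-fat diet for 16 weeks, starting at 6 to 8 weeks of age. The labels place 3 mice in each of 3 groups: floxed controls with an intact gene for protease-activated receptor 2 (WT), mice that lack the receptor in hepatocytes (dHep) and mice that lack it in the whole body (KO). PAR2 is a cell-surface receptor that coagulation proteases and other serine proteases switch on by cleavage, and the series title names it together with dyslipidemia, obesity, fatty liver disease and the hepatocyte transcription factor HNF4A. Reads assigned to genes came to 24493607, 25213844 and 25570388 in the WT libraries, 30509242, 26713161 and 23104686 in dHep, and 22275299, 22617238 and 18683660 in KO. Between 14999 and 15847 genes had at least 1 read in a library. On the first principal component, which held 47.9% of the variance, WT libraries lay between -62.2 and -49.5, dHep libraries between -6.08 and 24.7 and KO libraries between 45.9 and 49.8. The X-inactivation transcript Xist had 0 to 3 reads per library and the Y-linked gene Ddx3y 1080 to 2583. The Y-linked genes Eif2s3y, Kdm5d and Uty had 1186 to 2211, 337 to 847 and 279 to 740 reads. All were chosen after their values were seen, because the labels give no sex. These values argue against female mice in any group, and so against a difference in sex behind the male-biased and female-biased lists below.

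Counts of the targeted gene did not show the loss that the label of 1 group names. F2rl1, which encodes PAR2, spans positions 95511730 to 95525240 of mm10 chromosome 13, on the minus strand, and has 2 exons. It had 17, 27 and 28 reads in the WT libraries, 2, 8 and 0 in dHep, and 71, 103 and 76 in the libraries labelled KO. Mean abundance was 0.879 ± 0.208 CPM (SD, n = 3) in WT, 0.127 ± 0.171 in dHep and 4.13 ± 0.698 in the libraries labelled KO. F2rl1 fell in dHep against WT, with a log2 fold change of -2.73 ± 0.66 (SE; edgeR adjusted p = 0.0164). That call ended without WT replicate 2 (edgeR adjusted p = 0.0595), WT replicate 3 (0.062) or dHep replicate 1 (0.0505), and the range over all alternatives was 0.000109 to 0.062. Without dHep replicate 2, which held 8 of the 10 reads in dHep, 2 reads were left and the log2 fold change was -4.40 against WT (WT to dHep ratio 23.7, 95% counting interval 6.33 to 199) and 6.63 in the libraries labelled KO against dHep (ratio 111, interval 30.3 to 918). In the libraries labelled KO it rose against WT by 2.22 ± 0.51 on the log2 scale (edgeR adjusted p = 0.00735) and against dHep by 4.96 ± 0.64 (edgeR adjusted p = 0.00288). Counts are per whole gene, so reads over the deleted part and over the remaining part were not separated here. F2r, the thrombin receptor gene next to F2rl1, fell in dHep against WT (-0.89 ± 0.099) and rose in the libraries labelled KO against dHep (1.23 ± 0.10). F2rl1 was thus not lower in the libraries labelled KO. Every direction given for them rests on a genotype that these counts do not bear out. Whole-gene counts cannot refute it either, since transcripts of the targeted allele may be counted at the gene.

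**Figure D1:**
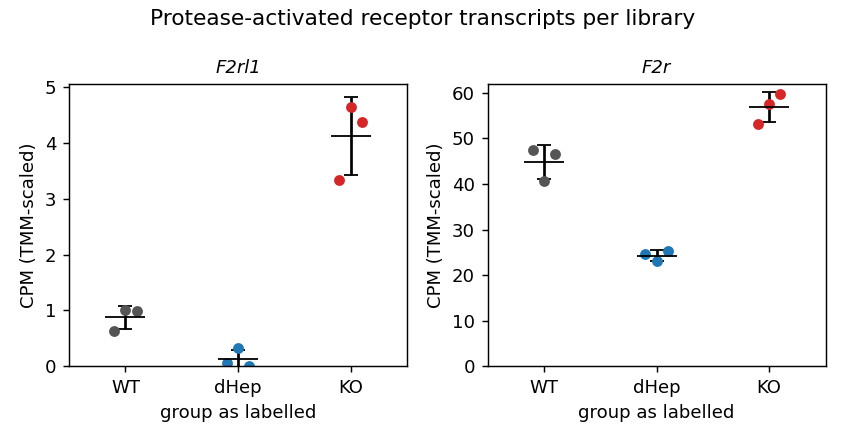
Transcripts of the PAR2 gene F2rl1 and of its neighbour F2r in CPM (vertical axis, from 0), per library (points) with the mean and SD of the 3 libraries of each labelled group (bars). F2rl1 averages 0.879 in WT, 0.127 in dHep and 4.13 in the libraries labelled KO.

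The comparison of dHep with floxed controls asks what loss of PAR2 in hepatocytes does to the whole liver on a high-fat diet. RNA of whole liver cannot tell fewer cells of a type from less RNA per cell. In dHep livers, 27 of 36 matrix, 23 of 28 cell-cycle and 13 of 20 monocyte and lipid-associated macrophage genes fell, and 17 of 24 male-biased and 17 of 27 amino acid metabolism genes rose. As lists these passed with the preset correlation of camera, and not with an estimated one (adjusted p = 0.104 for each). Col1a1, a chain of type I collagen, was 5.47-fold lower in dHep than in WT, and Cd36, a fatty acid uptake receptor, was 6.56-fold lower. Hsd3b5, a male-biased liver steroid dehydrogenase, stood at 243.5 ± 33.9 CPM in dHep and 0.460 ± 0.486 CPM in WT (SD, n = 3). Of 13141 genes tested, 1624 rose and 1568 fell, 3192 in all, at an adjusted p under 0.05. The count was 1952 without WT replicate 1 (890 rises), 1438 without WT replicate 2 (667 rises and 771 falls) and 1359 without WT replicate 3 (606 rises and 753 falls). WT replicate 1 and dHep replicate 2 also held transcripts of pancreatic enzymes (summed 376 and 1500 CPM, at most 5.08 in the others), and dHep replicate 2 those of skeletal muscle (844 CPM, at most 74.2 in the others). Without both libraries, an alternative added after the data were seen, 1399 genes rose and 1441 fell.

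Among the readouts fixed beforehand, Hnf4a itself did not pass the test in dHep against WT (log2 fold change 0.31 ± 0.13, edgeR adjusted p = 0.105; range over alternatives 0.0313 to 0.353, past the threshold by DESeq2). Cd36 and Col1a1 fell (-2.71 ± 0.20 and -2.45 ± 0.27). Apob, the structural protein of very-low-density lipoprotein, fell by 0.82 ± 0.18 on the log2 scale. Its edgeR adjusted p was 0.0109, and 0.0543 with only the 2 groups in the fit (range 4.29e-09 to 0.0543). Fasn, fatty acid synthase, fell (-1.26 ± 0.36, edgeR adjusted p = 0.0308; range 0.00134 to 0.123). That call ended without WT replicate 2 (edgeR adjusted p = 0.123, log2 fold change -0.83), WT replicate 3 (0.077), dHep replicate 1 (0.0815), dHep replicate 3 (0.0921) or KO replicate 3 (0.0509), and with limma voom or only the 2 groups in the fit. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose (1.55 ± 0.49, edgeR adjusted p = 0.0462), but the call ended under 12 of 17 alternatives (range 0.00207 to 0.174). Leaving out any library except dHep replicate 1 ended it, with edgeR adjusted p of 0.108, 0.156 and 0.105 without WT replicates 1, 2 and 3, 0.104 and 0.124 without dHep replicates 2 and 3, and 0.0607, 0.0638 and 0.0604 without KO replicates 1, 2 and 3. Alb (0.28 ± 0.33) did not pass.

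The largest rises in dHep were in Hsd3b5 (log2 fold change 9.05 ± 0.48), the major urinary protein genes Mup7 (6.68 ± 1.15) and Mup1 (5.42 ± 0.82), the organic anion carrier Slco1a1 (5.39 ± 0.79), the adhesion receptor Gpr110 (5.31 ± 0.59) and the cytochrome P450 gene Cyp2c54 (5.24 ± 0.70). The largest falls were in the collagenase gene Mmp13 (-6.28 ± 0.43), the macrophage elastase gene Mmp12 (31.9-fold lower), the cornified-envelope gene Sprr1a (-5.78 ± 0.54), the glutathione transferase gene Gsta1 (-5.52 ± 0.52), the ephrin receptor gene Ephb2 (-5.29 ± 0.57) and Gpnmb (-4.85 ± 0.46), a glycoprotein of lipid-laden macrophages. Without WT replicate 1 the rises were 10.35 (Hsd3b5), 9.34 (Mup7), 6.88 (Mup1), 7.04 (Slco1a1) and 6.56 (Cyp2c54), and without WT replicate 2 Gpr110 rose by 5.93. Without dHep replicate 1 Mmp12 fell by 6.05, and Sprr1a, with 9 reads left in dHep, was 37.3-fold lower (95% counting interval 19.5 to 82.1). Without dHep replicate 2 Ephb2 fell by 6.33, and Sprr1a, with 3 reads left in dHep, was 133-fold lower (interval 45.3 to 646). Ephb2 no longer passed with limma voom (adjusted p = 0.0604; range 2.12e-20 to 0.0604). Urinary protein, Cyp2 and glutathione transferase genes belong to families of near-identical members, so the split of reads within each family is uncertain.

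Of 34 gene lists tested in dHep against WT, 5 moved up and 14 down by camera with its preset correlation, and with an estimated correlation none passed (lowest adjusted p = 0.104, 8 lists under 0.05 unadjusted). Of 36 fibrosis and matrix genes, 27 fell and 0 rose (32 fell adjusted over the list alone), among them Mmp13 and the basement-membrane collagen gene Col4a2 (-1.75 ± 0.12). The camera adjusted p was 4.7e-27 (adjusted p = 0.104 with an estimated correlation). Of 28 proliferation genes, 23 fell and 1 rose (24 and 1 adjusted over the list alone), with falls in the cycling-cell antigen Mki67 (-2.60 ± 0.21) and the topoisomerase Top2a (-2.97 ± 0.27). Against all other genes, the list had a camera adjusted p of 2.29e-20 (adjusted p = 0.104 with an estimated correlation). Of 24 male-biased liver genes, 17 rose and 0 fell, the same counts adjusted over the list alone, including Hsd3b5 (10.35 without WT replicate 1) and Susd4 (2.72 ± 0.27). By camera the adjusted p was 1.45e-17 (adjusted p = 0.104 with an estimated correlation). Monocyte and lipid-associated macrophage markers fell in 13 of 20 genes and rose in 0 (14 fell adjusted over the list alone), with the integrin gene Itgax (-2.81 ± 0.23) and the chemokine receptor gene Cx3cr1 (-2.63 ± 0.23). This list had a camera adjusted p of 3.94e-16 (adjusted p = 0.104 with an estimated correlation). Amino acid and urea metabolism rose in 17 of 27 genes and fell in 0 (18 rose adjusted over the list alone), with Gnmt (1.70 ± 0.14), which uses S-adenosylmethionine to methylate glycine, and Hpd (1.43 ± 0.16) of tyrosine breakdown. Camera gave an adjusted p of 2.45e-10 (adjusted p = 0.104 with an estimated correlation). Female-biased liver genes fell in 12 of 22 and rose in 0 (13 fell adjusted over the list alone), with the organic anion transporter gene Slc22a27 (-3.62 ± 0.28) and Cyp2b13 (-3.33 ± 0.48; -2.72 without WT replicate 2). As a list they had a camera adjusted p of 9.06e-08 (adjusted p = 0.272 with an estimated correlation).

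Lipid and hepatocyte lists followed in dHep against WT. Lipid uptake, droplet and PPARG target genes fell in 9 of 26 and rose in 2 (10 and 3 adjusted over the list alone), with Cidec, a lipid-droplet fusion protein, down (-4.45 ± 0.30). In the camera test the list had an adjusted p of 1.75e-06 (adjusted p = 0.104 with an estimated correlation). Of 40 HNF4A-dependent hepatocyte genes, 19 rose and 7 fell, both over all genes and adjusted over the list alone. The camera adjusted p was 0.00029, and adjusted p = 0.586 with an estimated correlation. Apom, an apolipoprotein of high-density lipoprotein, rose (1.12 ± 0.12), while Apoa4, which rides on chylomicrons, fell (-3.46 ± 0.34). Fetal or dedifferentiated hepatocyte genes fell in 7 of 19 and rose in 0 (8 fell adjusted over the list alone), led by the annexin Anxa2 (-3.03 ± 0.14). For these genes as a list, camera gave an adjusted p of 8.1e-06 (adjusted p = 0.104 with an estimated correlation). Pericentral hepatocyte markers rose in 10 of 22 and fell in 2 (12 and 2 adjusted over the list alone), led by Cyp2c37 (2.30 ± 0.28). Testing the list by camera gave an adjusted p of 0.000296 (adjusted p = 0.467 with an estimated correlation). De novo lipogenesis fell in 8 of 25 genes and rose in 2 (11 and 2 adjusted over the list alone), led by the fatty acid elongase Elovl5 (-1.96 ± 0.26), and bile acid genes rose in 13 of 30 and fell in 4 (13 and 5 adjusted over the list alone), led by Cyp2c70 (1.96 ± 0.26), which makes muricholic acids. Fatty acid oxidation and PPARA targets fell in 7 of 36 and rose in 4 (12 and 6 adjusted over the list alone), led by the pantetheinase Vnn1 (-1.88 ± 0.15). For these 3 lists the camera adjusted p was 0.00874, 0.0112 and 0.0122, and adjusted p = 0.589, 0.547 and 0.698 with an estimated correlation. Without dHep replicate 1 the lipogenesis and fatty acid oxidation calls ended (camera adjusted p = 0.0945 and 0.271, ranges 3.09e-09 to 0.589 and 1.11e-05 to 0.698), and without dHep replicate 3 the bile acid call (0.114, range 0.000202 to 0.547). The 2 lipogenesis genes that rose encode transcription factors, Srebf1 (0.90, edgeR adjusted p = 0.0101, range 5.12e-05 to 0.0643) and Mlxipl (124.6 to 236.2 CPM in dHep, 82.56 to 100.7 CPM in WT). The 4 rising oxidation genes included the beta-oxidation enzymes Eci2 (0.55, edgeR adjusted p = 0.0159, range 0.00077 to 0.0778) and Acaa1a (0.68, edgeR adjusted p = 0.0226, range 0.00327 to 0.096).

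Immune, stress and other cell-type lists also moved in dHep against WT. Inflammatory cytokines and chemokines fell in 13 of 24 and rose in 2 (19 and 3 adjusted over the list alone), led by Cxcl10, an interferon-induced chemokine (-1.79 ± 0.26). This list had a camera adjusted p of 1.29e-05 (adjusted p = 0.137 with an estimated correlation). Stellate cell and fibroblast markers fell in 8 of 23 and rose in 1 (9 and 1 adjusted over the list alone), led by the type III collagen gene Col3a1 (-2.37 ± 0.18). Camera gave an adjusted p of 0.000175 (adjusted p = 0.467 with an estimated correlation). Unfolded protein and oxidative stress genes fell in 5 of 28 and rose in 2, the same counts adjusted over the list alone, led by Srxn1 (-1.63 ± 0.18), an NRF2 target. As a list they had a camera adjusted p of 0.00762 (adjusted p = 0.445 with an estimated correlation). The 2 that rose were genes of the unfolded protein response, Atf4 (0.73, edgeR adjusted p = 0.0165, range 0.00141 to 0.0737) and Xbp1 (0.65, edgeR adjusted p = 0.0355, range 0.00572 to 0.135). Interferon-stimulated genes fell in 9 of 31 and rose in 1, the same counts adjusted over the list alone, led by Ifit2 (-1.23 ± 0.13). Acute-phase genes fell in 8 of 30 and rose in 3 (9 and 5 adjusted over the list alone), led by lipocalin, Lcn2 (-3.20 ± 0.30), and endothelial markers fell in 5 of 23 and rose in 0 (3 fell adjusted over the list alone), led by the angiopoietin receptor Tek (-0.64 ± 0.13). For the last 3 lists the camera adjusted p was 0.00874, 0.0433 and 0.0433, and adjusted p = 0.467, 0.698 and 0.698 with an estimated correlation. The interferon call ended without dHep replicate 2 (camera adjusted p = 0.0864) and without WT replicate 1 and dHep replicate 2 together (0.0652; range 0.00209 to 0.467). The acute-phase call ended without dHep replicate 1 (0.584) or KO replicate 2 (0.0504; range 0.00682 to 0.698), and the endothelial call without WT replicate 1 (0.104), dHep replicate 1 (0.0952) or dHep replicate 3 (0.0626; range 0.00786 to 0.698). Among the lists that did not pass, median, mean and test differed in sign for coagulation, neutrophil, cholangiocyte and Kupffer cell genes. Immediate-early genes did not pass as a list (camera adjusted p = 0.192), but Egr1, a factor induced within minutes of a stimulus, stood at 78.1 to 104 CPM in the dHep libraries and 6.35 to 9.34 CPM in WT.

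**Figure D2:**
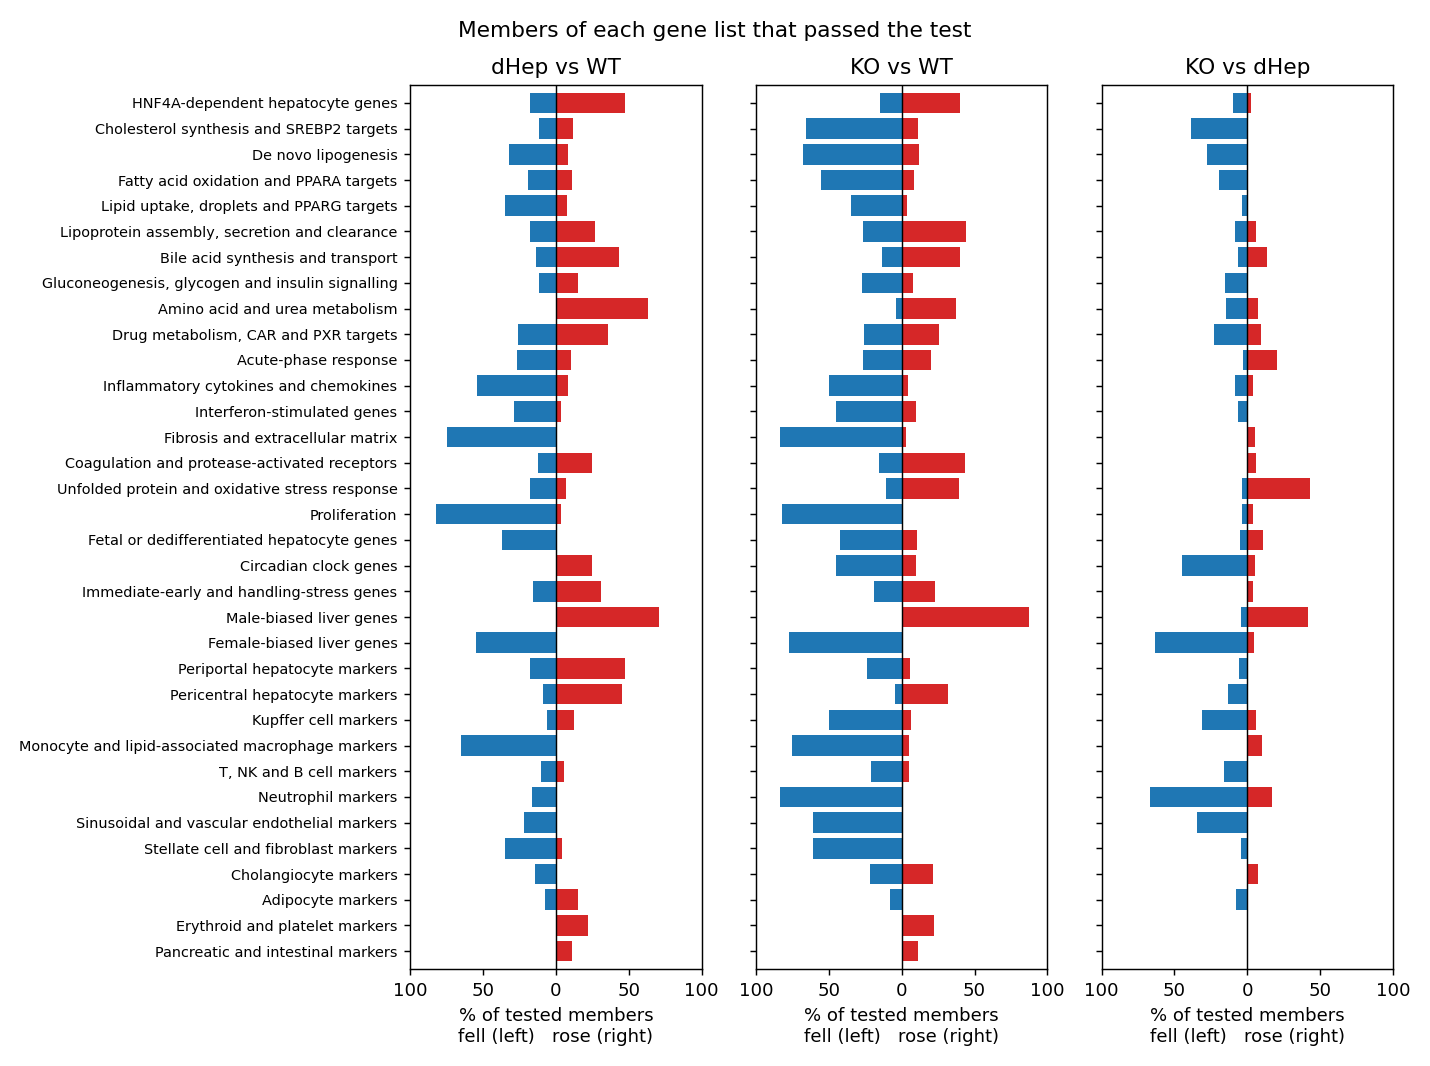
Percent of the tested members of each of 34 gene lists that fell (blue, left) or rose (red, right) at an edgeR adjusted p under 0.05, in each comparison. Of 36 fibrosis and matrix genes, 27 fell in dHep against WT and 30 in the libraries labelled KO against WT. Of all 13141 genes tested, 24.3% were called in dHep against WT, 43% in KO against WT and 9.62% in KO against dHep.

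The whole-body comparison asks what loss of PAR2 in every cell does to the same liver; here the directions are those of libraries labelled KO, in which F2rl1 was higher than in WT. Against WT, 21 of 24 male-biased genes rose. Falls came to 17 of 22 female-biased, 30 of 36 matrix, 23 of 28 cell-cycle, 15 of 20 monocyte and lipid-associated macrophage, 17 of 25 lipogenic (3 rose) and 17 of 26 cholesterol synthesis genes (3 rose). None of these lists passed with an estimated correlation (lowest adjusted p = 0.227; 0.379 for lipogenesis and 0.443 for cholesterol synthesis). Cyp2b9, a female-biased cytochrome P450, fell from 469.4 ± 120 CPM in WT to 0.115 ± 0.0209 CPM (SD, n = 3), a total of 7 reads against 38372. Hsd3b5 rose to 604.2 ± 66.5 CPM (log2 fold change 10.36, and 11.66 without WT replicate 1). Of 13141 genes tested, 2751 rose and 2902 fell, 5653 in all. Without WT replicate 3 the rises numbered 1794. With WT replicate 1 and dHep replicate 2 left out together, 2422 rose and 2621 fell. That alternative keeps KO libraries that also held members of the pancreatic and intestinal list. Vil1 stood at 39.3 CPM in KO replicate 1 (at most 1.28 in the others). Ins2 stood at 25 CPM in KO replicate 3 (at most 0.611 in the others).

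Hnf4a did not pass the test in the libraries labelled KO against WT (log2 fold change 0.32 ± 0.13, edgeR adjusted p = 0.0692). It passed without dHep replicate 2 (edgeR adjusted p = 0.0351) or dHep replicate 3 (0.0373), by DESeq2 and limma voom and with only the 2 groups in the fit (range 0.00398 to 0.193). Fasn (-1.93 ± 0.36), Cd36 (-2.85 ± 0.20) and Col1a1 (-2.00 ± 0.27) fell. Alb (-0.05 ± 0.33), Cyp7a1 (-0.68 ± 0.49) and Apob (-0.36 ± 0.18) did not pass. Cyp7a1 passed under 2 of 17 alternatives, without dHep replicate 1 (edgeR adjusted p = 0.0439) and with only the 2 groups in the fit (0.0389; range to 0.523). Apob passed under 4, without dHep replicate 3 (edgeR adjusted p = 0.0496), with only the 2 groups in the fit (0.0107), by DESeq2 (0.0144) and by limma voom (0.00504; range to 0.314).

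The largest rises in the libraries labelled KO were in Moxd1, a monooxygenase-like gene with no read in WT and 905 in KO (at least 406-fold higher against a floor of 3 reads per group), Hsd3b5 (log2 fold change 10.36 ± 0.50), Gm600 (2 reads against 1220, ratio 820, counting interval 227 to 6780), Mup7 (8.27 ± 1.23), the eosinophil-type ribonuclease gene Ear11 (1 read against 273, ratio 367, interval 65.3 to 14600) and Mup14 (7.47 ± 1.03). Among the falls, Cyp2b9 (-11.93 ± 0.47) stood first. Cebpe, a granulocyte transcription factor, had 529 reads in WT and 0 in KO, at least 131-fold lower. Cyp2b13 had 3333 and 2 reads (ratio 1240, interval 343 to 10200), and Lrit2 461 and 1 (ratio 343, interval 61.2 to 13600). Srd5a2, a steroid 5-alpha-reductase, had 144 and 0 reads, at least 35.7-fold lower, and Dct, an enzyme of melanin synthesis, 130 and 0 reads, at least 32.2-fold lower. Without WT replicate 1 the log2 fold changes were 11.66 (Hsd3b5), 10.93 (Mup7) and 8.90 (Mup14), and Ear11, left with no read in WT, was at least 82.5-fold higher. Without WT replicate 2 the Cyp2b13 ratio was 815 (interval 225 to 6740), and Gm600, left with no read in WT, was at least 366-fold higher. Without WT replicate 3 the ratios were 538 (Gm600, interval 149 to 4450) and 241 (Ear11, 42.9 to 9550), and Moxd1 was at least 266-fold higher. Without KO replicate 1 Cebpe, Srd5a2 and Dct were at least 85.2-fold, 23.2-fold and 20.9-fold lower and the Lrit2 ratio was 223 (39.8 to 8810). Without KO replicate 2 these were 83.4, 22.7, 20.5 and 218 (38.9 to 8630), and Moxd1 was at least 235-fold higher. Without KO replicate 3 Lrit2, left with no read in KO, was at least 81.7-fold lower. The floor stays at 3 reads per group, so a group of fewer libraries lowers these bounds by itself. Intervals are 95% and cover counting error only, and reads of the Mup, Cyp2b and Ear families may be split uncertainly between members.

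By camera with its preset correlation, 5 lists moved up and 15 down in the libraries labelled KO against WT, and none passed with an estimated correlation (lowest adjusted p = 0.227, 6 lists under 0.05 unadjusted). Male-biased liver genes rose in 21 of 24 and fell in 0, the same counts adjusted over the list alone, with the oxysterol hydroxylase Cyp7b1 (3.77 ± 0.34) beside Hsd3b5 (11.66 without WT replicate 1). The camera adjusted p was 3.46e-23 (adjusted p = 0.227 with an estimated correlation). Female-biased genes fell in 17 of 22 and rose in 0 (18 and 1 adjusted over the list alone), with Cyp2b9 and Slc22a27 (-5.83 ± 0.33). Against all other genes, the list had a camera adjusted p of 8.33e-19 (adjusted p = 0.227 with an estimated correlation). Fibrosis and matrix genes fell in 30 of 36 and rose in 1, the same counts adjusted over the list alone, with Col6a3 (-1.96 ± 0.15) and Col3a1 (-2.20 ± 0.18). This list had a camera adjusted p of 1.28e-15 (adjusted p = 0.227 with an estimated correlation). Proliferation genes fell in 23 of 28 and rose in 0 (24 fell adjusted over the list alone), with Mki67 (-2.07 ± 0.20) and the replication helicase subunit Mcm3 (-1.31 ± 0.15). Camera gave an adjusted p of 2.11e-09 (adjusted p = 0.262 with an estimated correlation). Monocyte and lipid-associated macrophage markers fell in 15 of 20 and rose in 1 (16 and 1 adjusted over the list alone), with Itgax (-2.69 ± 0.23) and Cx3cr1 (-2.55 ± 0.23). As a list they had a camera adjusted p of 4.41e-09 (adjusted p = 0.227 with an estimated correlation). De novo lipogenesis fell in 17 of 25 and rose in 3 (17 and 4 adjusted over the list alone), with acetyl-CoA carboxylase, Acaca (-2.49 ± 0.26), and Elovl5 (-2.56 ± 0.27). For these genes as a list, camera gave an adjusted p of 1.02e-05 (adjusted p = 0.379 with an estimated correlation).

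Further metabolic lists moved in the libraries labelled KO against WT. Cholesterol synthesis and SREBP2 targets fell in 17 of 26 and rose in 3 (19 and 3 adjusted over the list alone), led by HMG-CoA synthase, Hmgcs1 (-2.46 ± 0.27). In the camera test the list had an adjusted p of 6.9e-05 (adjusted p = 0.443 with an estimated correlation). Fatty acid oxidation and PPARA targets fell in 20 of 36 and rose in 3, the same counts adjusted over the list alone, led by Vnn1 (-2.08 ± 0.15). This list had a camera adjusted p of 9.41e-05 (adjusted p = 0.536 with an estimated correlation). The 3 rising genes included the beta-oxidation enzymes Acads (0.53, edgeR adjusted p = 0.0169, range 0.000542 to 0.0638) and Acaa2 (0.53, edgeR adjusted p = 0.0287, range 0.000468 to 0.0955). Lipid uptake, droplet and PPARG targets fell in 9 of 26 and rose in 1, the same counts adjusted over the list alone, led by Cd36. Camera gave an adjusted p of 0.000223 (adjusted p = 0.262 with an estimated correlation). Amino acid and urea metabolism rose in 10 of 27 and fell in 1 (9 and 1 adjusted over the list alone), led by the hydroxyproline oxidase Prodh2 (1.33 ± 0.11). As a list they had a camera adjusted p of 0.000207 (adjusted p = 0.379 with an estimated correlation). HNF4A-dependent genes rose in 16 of 40 and fell in 6, the same counts adjusted over the list alone, led by the antitrypsin gene Serpina1a (1.78 ± 0.21), one of several close copies. The camera adjusted p was 0.00523 (adjusted p = 0.588 with an estimated correlation). Bile acid genes rose in 12 of 30 and fell in 4, the same counts adjusted over the list alone, led by Cyp7b1, and coagulation genes rose in 14 of 32 and fell in 5 (16 and 5 adjusted over the list alone), led by factor XI, F11 (1.54 ± 0.15). The 14 rising coagulation genes include F2rl1 and its neighbour F2r, both receptors on this list. For the last 2 lists the camera adjusted p was 0.00632 and 0.00853, and adjusted p = 0.443 and 0.54 with an estimated correlation. Fetal or dedifferentiated hepatocyte genes fell in 8 of 19 and rose in 2, the same counts adjusted over the list alone, led by Anxa2 (-2.46 ± 0.13). Testing the list by camera gave an adjusted p of 0.00262 (adjusted p = 0.373 with an estimated correlation).

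Endothelial, stellate cell, Kupffer cell and neutrophil lists moved down in the libraries labelled KO against WT. Endothelial markers fell in 14 of 23, led by Tek (-1.21 ± 0.14), and stellate cell and fibroblast markers in 14 of 23, led by Col3a1; neither list had a rise, and adjusted over the list alone 14 and 15 fell. Kupffer cell markers fell in 8 of 16 and rose in 1, the same counts adjusted over the list alone, led by the macrophage secreted protein Cd5l (-2.15 ± 0.28), and neutrophil markers fell in 5 of 6 and rose in 0 (6 fell adjusted over the list alone), led by Lcn2 (-1.90 ± 0.28). Lcn2 is also on the acute-phase list and fell further in dHep, where 1 of 6 neutrophil markers fell. Across these 4 lists the camera adjusted p was 5.91e-05, 9.25e-05, 0.00706 and 0.00632, and adjusted p = 0.443, 0.443, 0.54 and 0.379 with an estimated correlation. Inflammatory cytokines and chemokines fell in 12 of 24 and rose in 1, the same counts adjusted over the list alone, led by Cxcl9 (-2.28 ± 0.32), a chemokine for T cells. This list had a camera adjusted p of 0.000913 (adjusted p = 0.369 with an estimated correlation). Interferon-stimulated genes fell in 14 of 31 and rose in 3 (15 and 3 adjusted over the list alone), led by Ifit2 (-1.80 ± 0.14). Camera gave an adjusted p of 0.0225 (adjusted p = 0.505 with an estimated correlation). That call ended without KO replicate 1 (camera adjusted p = 0.0968) and with only the 2 groups in the fit (0.0552; range 0.00517 to 0.505). Median, mean and test differed in sign for lipoprotein, periportal, acute-phase, adipocyte, gluconeogenesis, and pancreatic and intestinal genes, none of which passed as a list. Egr1 stood at 91.6 CPM in KO replicate 1, and at 11.6 and 13.3 CPM in KO replicates 2 and 3.

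**Figure D3:**
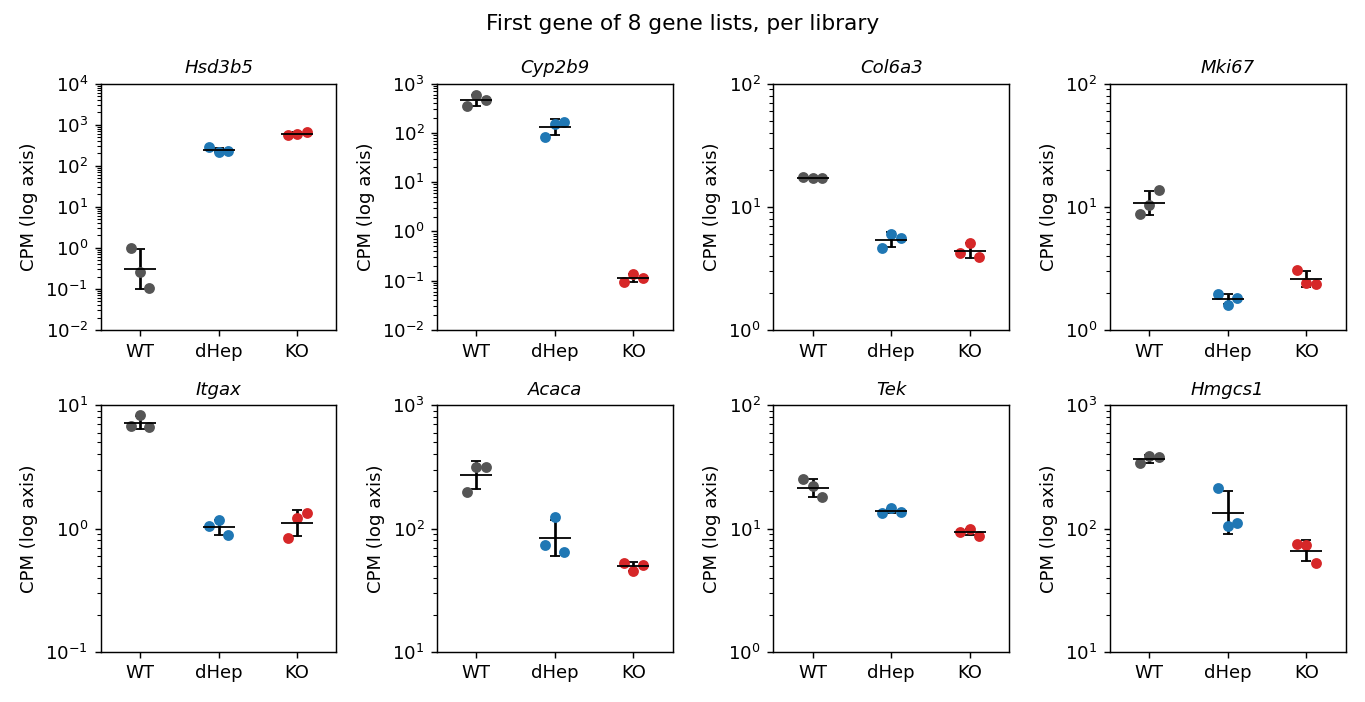
CPM on a log axis for the first gene of the 8 gene lists with the lowest list p in the libraries labelled KO against WT, leaving out repeats; points are libraries, bars the geometric mean and SD of 3 libraries on the log scale. Hsd3b5 lies between 548.5 and 677.8 in the libraries labelled KO, and Cyp2b9 between 0.0939 and 0.136.

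The libraries labelled KO were also set directly against dHep, the comparison that tests where these 2 groups differ. Directions again rest on a label that the whole-gene F2rl1 counts do not bear out. Falls in the libraries labelled KO came to 14 of 22 female-biased, 10 of 26 cholesterol synthesis, 9 of 20 clock and 8 of 23 endothelial genes, and 12 of 28 stress-response genes rose. None of these lists passed with an estimated correlation (lowest adjusted p = 0.278). Per3, a clock repressor, was 5.06-fold lower, and Asns, the asparagine synthetase induced by amino acid shortage, was 9.81-fold higher. In all, 556 genes rose and 708 fell, 1264 together. The count moved with single libraries: it was 807, 692 and 722 without WT replicates 1, 2 and 3, 2809 without dHep replicate 3, and 419 and 386 without KO replicates 2 and 3. Without dHep replicate 2 the falls numbered 462. Leaving out WT replicate 1 and dHep replicate 2 together, an alternative added after the data were seen, left 230 rises and 265 falls. DESeq2 called 2016 genes, limma voom 802, and a fit with only these 2 groups 342.

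Of the fixed readouts, F2rl1 rose and Cyp7a1 fell (-2.22 ± 0.50, edgeR adjusted p = 0.0264). The Cyp7a1 call ended without dHep replicate 2 (edgeR adjusted p = 0.0658) or KO replicate 1 (0.071), 2 (0.105) or 3 (0.0667), among 7 of 17 alternatives (range 0.00114 to 0.105). Hnf4a (0.01 ± 0.13), Alb (-0.33 ± 0.33), Apob (0.46 ± 0.18), Fasn (-0.68 ± 0.35), Cd36 (-0.14 ± 0.19) and Col1a1 (0.45 ± 0.27) did not pass; Apob passed without dHep replicate 3 (edgeR adjusted p = 0.032) and by DESeq2 (0.00396; range to 0.306). Beyond F2rl1, the largest rises were in Moxd1 (2 reads against 905, ratio 586, interval 162 to 4850), the serpin gene Serpina3c (7.89 ± 0.26), Gm600 (7.37 ± 0.60), Ear11 (5.74 ± 0.96) and the ubiquitin ligase gene Lnx1 (5.04 ± 0.42). Cyp2b9 (-10.13 ± 0.46), Cebpe (429 reads against 0, at least 110-fold lower), Dct (272 against 0, at least 70-fold lower), Srd5a2 (162 against 0, at least 41.7-fold lower), Lrit2 (611 against 1, ratio 472, interval 84.4 to 18700) and 1810053B23Rik (175 against 1, ratio 135, interval 23.9 to 5370) had the largest falls. Single libraries moved some of these values. Without dHep replicate 1 the log2 fold changes were 6.63 (Gm600) and 5.02 (Ear11), and the Moxd1 ratio was 337 (interval 93.1 to 2790). Without dHep replicate 2 F2rl1 stood at 6.63. Without dHep replicate 3 the Gm600 ratio was 390 (interval 133 to 1890). In that setting Ear11 and Moxd1, left with no read in dHep, were at least 87.3-fold and 289-fold higher, and Dct was at least 34.1-fold lower. Without KO replicate 1 Cebpe, Dct and Srd5a2 were at least 71.7-fold, 45.5-fold and 27.1-fold lower, and the ratios of Lrit2 and 1810053B23Rik were 306 (interval 54.8 to 12100) and 87.8 (15.5 to 3490). Without KO replicate 2 the bounds were 70.2, 44.5 and 26.5, the ratios 300 (Lrit2, interval 53.6 to 11900) and 339 (Moxd1, 93.1 to 2810), and 1810053B23Rik was at least 28.6-fold lower. Without KO replicate 3 Lrit2 was at least 112-fold lower. Moxd1 did not pass with limma voom (adjusted p = 0.111; range 1.49e-05 to 0.111), and Dct did not pass without KO replicate 1 (edgeR adjusted p = 0.0574), 2 (0.0785) or 3 (0.0766), with the replicate number as a block (0.0632) or with only the 2 groups in the fit (0.0647; range 1.8e-07 to 0.0785).

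Between the libraries labelled KO and dHep, 4 lists moved up and 10 down by camera with its preset correlation, and none passed with an estimated correlation (lowest adjusted p = 0.278, 3 lists under 0.05 unadjusted). Female-biased genes fell in 14 of 22 and rose in 1 (17 and 1 adjusted over the list alone), with Cyp2b9 and the fatty acid hydroxylase Cyp4a14 (-2.12 ± 0.27). As a list they had a camera adjusted p of 1.31e-17 (adjusted p = 0.278 with an estimated correlation). Unfolded protein and oxidative stress genes rose in 12 of 28 and fell in 1 (17 and 1 adjusted over the list alone), with the endoplasmic reticulum chaperone Hyou1 (1.08 ± 0.15) and Asns (3.29 ± 0.51). For these genes as a list, camera gave an adjusted p of 8.35e-10 (adjusted p = 0.278 with an estimated correlation). The 1 that fell was the oxidative stress gene Hmox1 (-0.90, edgeR adjusted p = 0.0264, range 0.00112 to 0.113). Male-biased genes rose in 10 of 24 and fell in 1 (13 and 1 adjusted over the list alone), with Moxd1 and Cspg5 (3.28 ± 0.52). Against all other genes, the list had a camera adjusted p of 2.6e-08 (adjusted p = 0.719 with an estimated correlation). Cholesterol synthesis and SREBP2 targets fell in 10 of 26 and rose in 0 (11 fell adjusted over the list alone), with the mevalonate pathway kinase Pmvk (-1.11 ± 0.18) and squalene synthase, Fdft1 (-0.93 ± 0.16). This list had a camera adjusted p of 1.66e-06 (adjusted p = 0.719 with an estimated correlation). Clock genes fell in 9 of 20 and rose in 1 (11 and 1 adjusted over the list alone), with Per3 (-2.34 ± 0.22) and the clock output factor Tef (-1.26 ± 0.21). Camera gave an adjusted p of 7.71e-06 (adjusted p = 0.289 with an estimated correlation). Kupffer cell markers fell in 5 of 16 and rose in 1 (12 and 1 adjusted over the list alone), with the folate receptor Folr2 (-1.36 ± 0.26) and the ficolin Fcna (-1.18 ± 0.24). As a list they had a camera adjusted p of 4.6e-05 (adjusted p = 0.719 with an estimated correlation). Folr2 did not pass without KO replicate 2 (edgeR adjusted p = 0.0509; range 3.18e-05 to 0.0509), nor Fcna without KO replicate 2 (0.0535) or 3 (0.0589), with only the 2 groups in the fit (0.0585) or without WT replicate 1 and dHep replicate 2 together (0.0564; range 7.17e-05 to 0.0589).

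Further lists that differed between the libraries labelled KO and dHep had higher list p values. De novo lipogenesis fell in 7 of 25 and rose in 0 (8 fell adjusted over the list alone), led by the desaturase Fads1 (-1.68 ± 0.22), and endothelial markers fell in 8 of 23 and rose in 0, the same counts adjusted over the list alone, led by the sinusoidal lectin Clec4g (-1.24 ± 0.15). Acute-phase genes rose in 6 of 30 and fell in 1 (7 and 1 adjusted over the list alone), led by lipopolysaccharide-binding protein, Lbp (0.61 ± 0.11), while fatty acid oxidation genes fell in 7 of 36 and rose in 0 (8 fell adjusted over the list alone), led by Cyp4a14. Across these 4 lists the camera adjusted p was 0.000114, 0.000228, 0.000608 and 0.00402, and adjusted p = 0.719, 0.72, 0.72 and 0.882 with an estimated correlation. Periportal markers fell in 1 of 17, Gls2, the liver glutaminase (-0.81 ± 0.12), and rose in 0 (5 and 1 adjusted over the list alone). Among all 13141 genes tested 708 fell, so 1 of 17 is near the share of all genes. Neutrophil markers fell in 4 of 6 and rose in 1 (5 and 1 adjusted over the list alone), led by the granulocyte growth factor receptor Csf3r (-1.23 ± 0.23). Gluconeogenesis, glycogen and insulin signalling genes fell in 4 of 26 and rose in 0 (5 fell adjusted over the list alone), led by the insulin receptor Insr (-0.94 ± 0.13), and coagulation genes rose in 2 of 32, F2r and F2rl1, and fell in 0, the same counts adjusted over the list alone. Both are receptors on this list, not coagulation factors. For these last 4 lists the camera adjusted p was 0.0107, 0.012, 0.0307 and 0.0406, and adjusted p = 0.72, 0.719, 0.72 and 0.882 with an estimated correlation.

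Single libraries and settings ended some of these calls between the libraries labelled KO and dHep. Without dHep replicate 1 the acute-phase (camera adjusted p = 0.0503, range 2.38e-06 to 0.72), neutrophil (0.0537) and coagulation (0.76) calls ended. Without dHep replicate 3 the fatty acid oxidation (camera adjusted p = 0.455, range 1.19e-06 to 0.882), gluconeogenesis (0.263), periportal (0.144, range 3.08e-05 to 0.72) and coagulation (0.054) calls ended. Without KO replicate 1 the neutrophil (camera adjusted p = 0.0828, range 0.0113 to 0.719) and coagulation (0.065) calls ended, without KO replicate 2 the gluconeogenesis (0.0635) and coagulation (0.0501, range 0.000481 to 0.882) calls, and without KO replicate 3 the gluconeogenesis call (0.056, range 0.000386 to 0.72). Lbp did not pass with only the 2 groups in the fit (edgeR adjusted p = 0.0562, range 1.95e-05 to 0.0562). Csf3r did not pass without KO replicate 3 (edgeR adjusted p = 0.0612), without WT replicate 1 and dHep replicate 2 together (0.0512) or with only the 2 groups in the fit (0.0635; range 0.00112 to 0.0635). The neutrophil call also ended with the stricter low-count filter (camera adjusted p = 0.153) and with only the 2 groups in the fit (0.164), which ended the coagulation call as well (0.0517), as did the replicate number as a block (0.0609). Median, mean and test differed in sign for bile acid, fibrosis, fetal, lipoprotein, interferon, erythroid, lipid uptake and HNF4A-dependent genes, none of which passed as a list.

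**Figure D4:**
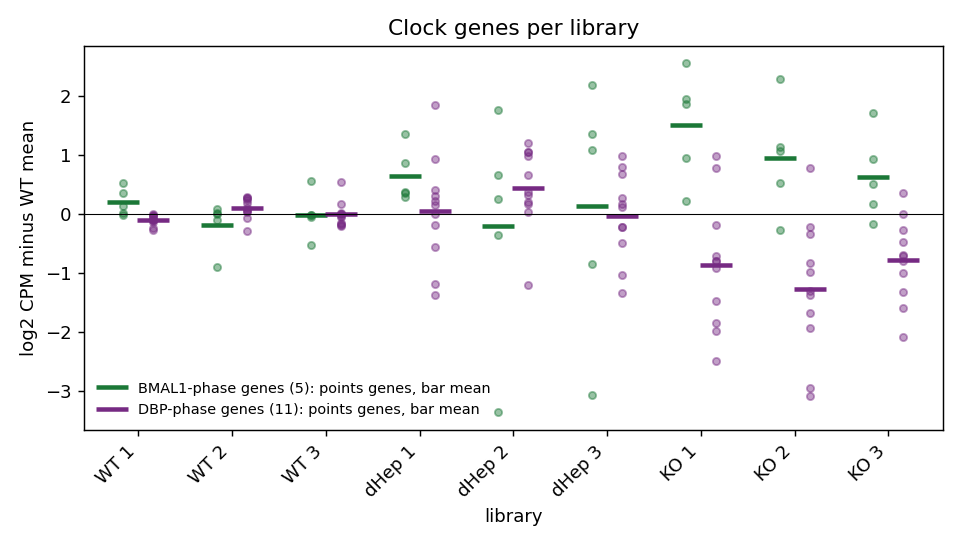
Log2 CPM minus the WT mean (vertical axis) per library, for 5 genes of the BMAL1 phase and 11 of the DBP phase of the circadian clock. Both sets were chosen after the data were seen. Points are genes, and each bar is the mean over the genes of a set in that library. In the libraries labelled KO against dHep, the BMAL1-phase genes averaged 0.52 and the DBP-phase genes -1.22 on the log2 scale.

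Much of the change against WT was called in both dHep and the libraries labelled KO, whose F2rl1 counts do not bear out the label. Of the genes tested, 1243 rose and 1216 fell in both, 2459 in all, against 340 and 346.3 for independent lists of these sizes; 30 genes were called in opposite directions. The 6 shared genes with the lowest p were Hsd3b5 (10.35 in dHep and 11.66 in the libraries labelled KO without WT replicate 1), Anxa2, the immediate-early gene Ier2 (log2 fold change 3.47 ± 0.21 in dHep and 3.51 ± 0.22 in the libraries labelled KO), Kbtbd11 (-3.70 ± 0.24 and -3.94 ± 0.24), the matrix protein tenascin, Tnc (-3.58 ± 0.23 and -3.34 ± 0.23), and Enho, which encodes the secreted peptide adropin (3.87 ± 0.26 and 3.76 ± 0.26). Across genes, which are not independent replicates, the log2 fold changes of both comparisons correlated with a Pearson r of 0.693, against 0.488 in 20 simulations of unchanged groups sharing the WT libraries, and their covariance was 0.58 against 0.0599 simulated. The shared count was 1525, 1114 and 1058 without WT replicates 1, 2 and 3. Groups of 3 controls cannot be divided so that each part keeps 2 libraries, so part of the excess may come from the shared WT libraries. Called in the same direction against both WT and dHep were 912 genes in the libraries labelled KO; this number was 569, 473 and 490 without WT replicates 1, 2 and 3, 607 and 2129 without dHep replicates 2 and 3, and 312 and 293 without KO replicates 2 and 3.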

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

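Leaving out WT replicate 1 and dHep replicate 2 together was chosen after the data were seen; the other alternatives were set beforehand. For the count of genes changed between KO and dHep, DESeq2 gave 2016 (871 rises, 1145 falls), a fit with only the 2 groups 342 (152, 190), limma voom 802 (358, 444) and leaving out both libraries 495 (230, 265). Leaving out 1 library at a time gave 386 to 2809 genes in this comparison (175 to 1313 rises, 211 to 1496 falls), 1359 to 4025 in dHep against WT (606 to 2060 rises, 753 to 1965 falls), 1794 to 3180 rises in KO against WT, and 1058 to 3236 genes in the overlap (484 to 1637 rises, 574 to 1599 falls). With an estimated correlation, camera called 0, 0 and 0 lists in dHep against WT, KO against WT and KO against dHep (lowest adjusted p = 0.104, 0.227 and 0.278; unadjusted p under 0.05 in 8, 6 and 3). With the replicate number as a block there were 2781 (genes changed, dHep vs WT), 5292 (genes changed, KO vs WT) and 954 (genes changed, KO vs dHep). No pairing by replicate number was seen, since 0 of 9 library correlations exceeded 0.1. With 3 libraries per group this cannot exclude a shared litter, cage or batch. Directions turned only for results that had not passed. A list's value is its mean log2 fold change, while its direction is that of camera, so the value can keep its sign. Without a low-count filter the turned values were 0.184 (Kupffer cell, dHep against WT) and -0.0597 (HNF4A-dependent), -0.0931 (inflammatory) and -2.17 (pancreatic and intestinal) in KO against dHep. With the stricter filter they were 0.12 (Kupffer cell) and 0.509 (adipocyte) in dHep against WT, and -0.0953 (lipid uptake) and -0.13 (inflammatory) in KO against dHep. With only the 2 groups they were 0.193 (adipocyte, dHep against WT), -2.57 (pancreatic and intestinal, KO against WT), -0.0945 (lipid uptake) and -0.13 (inflammatory, both KO against dHep). The block turned Kupffer cell markers in dHep against WT (0.0791) and inflammatory genes in KO against dHep (0.0588), and limma voom turned Cd36 in KO against dHep (0.02964). Leaving out both libraries turned adipocyte markers in dHep against WT (0.391) and, in KO against dHep, Pnlip (0.53), lipid uptake (0.125), stellate cell (0.0413) and pancreatic and intestinal genes (2.29). The cause was not tested. Leaving out 1 library at a time turned these in dHep against WT: adipocyte (0.445 to 1.39), drug metabolism (-0.133 to 0.272), Kupffer cell (-0.229 to 0.184), pancreatic and intestinal (-3.89 to 5.70) and clock phases (-0.25 to 0.542). In KO against WT it turned Alb (-0.08189 to 0.03661), adipocyte (-0.193 to 0.955), cholangiocyte (0.0169 to 0.81), gluconeogenesis (-0.385 to 0.0889) and pancreatic and intestinal genes (-4.05 to 2.34). In KO against dHep it turned Hnf4a (-0.06855 to 0.1238), Cd36 (-0.3068 to 0.07016), Pnlip (-9.29 to 0.45), Vil1 (-0.54 to 4.96), drug metabolism (-0.384 to 0.0196), erythroid (-0.156 to 0.22), fibrosis (0.029 to 0.29), HNF4A-dependent (-0.193 to 0.0963), immediate-early (-0.322 to 0.382), inflammatory (-0.0327 to 0.252), interferon (-0.16 to -0.00463), lipid uptake (-0.051 to 0.232), lipoprotein (-0.145 to 0.0344), monocyte (0.0131 to 0.318), pancreatic and intestinal (-5.92 to 2.27), pericentral (-0.388 to -0.0514) and stellate cell genes (-0.36 to 0.0411). Of the lists that had not passed, 8 of 15, 6 of 14 and 9 of 20 passed under at least 1 alternative in dHep against WT, KO against WT and KO against dHep, among them HNF4A-dependent genes in KO against dHep without dHep replicate 1 (camera adjusted p = 0.0201).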

Other observations

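The tests below were chosen only after the results were seen, except the test of libraries with pancreas and muscle transcripts and the splits of the mice. The test of a swap and the rule for DNA of another strain were moreover changed after first values of the positional test had been seen, and the rule for all-or-none genes after those genes had been seen.

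Clock genes went opposite ways in the libraries labelled KO. Arntl, the core activator BMAL1, stood at 6.35 to 11.4 CPM there, 2.33 to 4.98 CPM in dHep and 1.35 to 2.78 CPM in WT, while Per3 stood at 5.83 to 8.89, 29.5 to 46.5 and 20.1 to 27.3 CPM. Against dHep, Arntl was the 1 gene of the clock list called as rising (1.25, edgeR adjusted p = 0.049), and 9 fell. The Arntl call ended under 12 of 17 alternatives (range 0.00751 to 0.146). Within dHep, replicates 2 and 3 had 19 and 25.2 CPM of the repressor Cry1, and replicate 1 had 6.81 CPM. The immediate-early gene Fos stood at 9.71, 68.1 and 13.6 CPM in dHep and 30.6 CPM in KO replicate 1, and between 1.59 and 2.42 CPM in the other 5 libraries. Ier2 was between 2.67 and 3.03 CPM in WT and between 23.4 and 40 CPM in the other 6 libraries.

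F2rl1 had more reads in the libraries labelled KO than in WT, and the scaling between libraries is argued against, since the lowest log2 fold change over all alternatives was 2.04 (2.038). A swap of the WT and KO libraries stays open: with over 3 reads in every library and a mean of at least 1 CPM on one side, and on the other none in the group or at most 3 in all in the 6 other libraries, 5 genes set KO apart (Cebpe, Dct, Srd5a2, Moxd1 and H28) and 0 set WT apart (1-sided exact binomial p = 0.0312). With at most 3 reads allowed in the group too, 10 set KO apart and 2 set WT apart (Mup9 and Mup11, 1-sided exact binomial p = 0.0193). After a swap, however, a gene that depends on the receptor in either direction would set the libraries labelled KO apart too. The first version of that test, the share of genes near F2rl1 that set WT apart, gave a circular-shift p of 0.93, which speaks against a swap only if DNA of another strain lies there. The F2rl1 counts narrow a swap further. After a swap the libraries labelled WT would be the whole-body knockouts, yet they held 72 F2rl1 reads. The dHep libraries held 10 (WT to dHep ratio 6.93, counting interval 3.56 to 15.1). A swap alone thus leaves these reads unexplained, and would also need transcripts of the targeted allele counted at the gene. Without a swap, such transcripts may be counted as well. A change of 2.22 (2.223) over the whole gene cannot separate the deleted from the remaining part.

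Genes called in the same direction in KO against WT and against dHep were more frequent near F2rl1: 10 of 60 within 5 Mb, 16.7% against 6.88% elsewhere (permutation p by circular shifts of the gene order = 0.047, unadjusted among 15 tests of windows and gene sets), among them Papd4, Arsb, Lhfpl2 and F2r. Genes near the detection limit are weakly argued against by the permutation p of 0.026 among genes of 10 CPM or more. The permutation p of 0.041 between 1 and 5 Mb narrowly argues against an effect limited to 1 Mb. It cannot exclude a local effect reaching 2 Mb, since 8 of the 10 genes lie that near. Both p values are unadjusted and come from the main fit only. Within 2 Mb the share was 8 of 24 genes, 33.3% against 6.88% (permutation p = 0.0051), within 10 Mb the permutation p was 0.083, and the share within 5 Mb was 9.84% (3.51% elsewhere) without WT replicate 2, 9.84% (2.14%) without KO replicate 3, 10% (2.28%) without KO replicate 2 and 27.9% (15.8%) without dHep replicate 3. By whole chromosome, the share was highest on chromosome 14 (13.9% against 6.68%, permutation p = 0.021, Benjamini-Hochberg adjusted p = 0.42), where Cebpe and Dct lie, and chromosome 13 had 8.01% (permutation p = 0.25). DNA of another strain around the targeted locus may remain in the mice labelled KO, but it stays open, since the p over the alternatives ran from 0.012 to 0.072 and passed 0.05 without WT replicate 2 (0.072), WT replicate 3 (0.055) or dHep replicate 1 (0.053).

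Clock genes differed between KO and dHep: 5 BMAL1-phase genes exceeded 11 DBP-phase genes by 1.75 in mean log2 fold change (2-sided exact permutation p across genes = 0.0048, over alternatives up to 0.022), and by 1.98 in KO against WT (0.00092, up to 0.0037). Both sets were chosen after changes of clock genes had been seen and their genes are regulated together, so this p describes the difference and tests no cause. A different circadian phase at tissue collection and an effect of the genotype on the clock both stay open, since collection times are not in the labels. Libraries with pancreas and muscle transcripts are argued against, since 0.826 of the difference stayed without WT replicate 1 and dHep replicate 2. In dHep against WT the difference was 0.235 (exact permutation p = 0.45), -0.25 without dHep replicate 1 and 0.687 (exact permutation p = 0.033) without both libraries.

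Each comparison has 10 splits of its 6 mice, the real one included, too few for a share under 0.05; in each, 1 split (the real one) called as many genes. The real counts were 3192, 5653 and 1264 in dHep against WT, KO against WT and KO against dHep, and the highest of the other splits called 3, 0 and 50 genes by edgeR (846, 252 and 2513 at an unadjusted p under 0.05).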
